A study of Homo sapiens with 4 samples.

How the data were processed

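RNA from H1299 cells, an established human non-small cell lung cancer line, was sequenced from 4 cultures. The labels describe a knockdown of the splicing factor SRSF1 or a control, each left unirradiated or given 6 Gy of ionizing radiation. There was 1 library per group, so no difference has a replicate check. The submitters' processing notes name CASAVA 1.8.2, TopHat, Cufflinks and the build hg19, without roles or order. Library preparation used an Illumina TruSeq kit on total RNA, per the labels' protocols.

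The values come from 2 tables of skipped-exon events, 1 for the unirradiated and 1 for the irradiated pair of libraries. Their headers are those of a comparison by MISO, a program that estimates how often an exon is spliced in; its version, settings and exon annotation are not given in the sources used here. Per the file headers, the authors gave for each event and library the posterior mean fraction of transcripts that include the exon (PSI, percent spliced in, from 0 to 1), with the bounds of its 95% interval. The deposited score of difference is the first library's PSI minus the second's, and it equals the knockdown minus control difference used here for every event. The deposited Bayes factor is a ratio of the evidence for a PSI difference to that for none, per the file headers, and it is capped. The deposited tables also give reads per class as text, per the file headers: reads only possible with the exon included, reads only possible with the exon skipped, reads possible with either, and reads possible with neither. The columns carry generic names, so each was tied to its library by the name of the comparison and MISO's order of naming. All directions below rest on that order.

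PSI is a share within a library, so PSI was not scaled between libraries. Inclusion-only plus exclusion-only reads are called informative reads here. Scaled reads, used only in the closing section, were divided by the library's sum of informative reads and reads possible with either. That sum ran over all events for PTPMT1, and over exons measured in all 4 libraries for the correlation. An event was measured where each library held at least 10 informative reads and at least 1 read of each kind was seen over both libraries. For each distinct exon the event with most informative reads was kept. An exon was called where the Bayes factor was at least 10 and the absolute PSI difference at least 0.2. For irradiation the tables used hold no Bayes factor. An exon then counted as changed where PSI differed by at least 0.2 and the 95% intervals did not overlap, over exons measured in all 4 libraries. The difference between the 2 knockdown effects was tested per exon by a Wald test on the difference of log odds ratios of the reads, with 0.5 added to each cell and Benjamini-Hochberg adjustment at 0.05. An additive model of knockdown and irradiation was fitted with limma 3.58.1 in R 4.3.3 to log2 ratios of inclusion-only to exclusion-only reads, 0.5 added, with a trend, and called where the mean PSI difference was also at least 0.2. An alternative set beforehand weighted each ratio by the inverse of its counting variance. The weighted fit without the PSI minimum was added after seeing the data. Both treat the 2 irradiation states as the replicates of knockdown. Tests on reads cover counting error, and PCR copies are not independent molecules, so these tests compare the libraries, not the conditions.

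Gene lists, exon features and motif densities were set against 10000 random sets of the same size, matched on deciles of informative reads for lists and features, and on quintiles of exon length and informative reads for motifs. A percentile above 97.5 or below 2.5 was counted as standing apart. The 11 gene lists were splicing factors, reported SRSF1 splicing targets, DNA damage response and repair, apoptosis, cell cycle and mitosis, mitochondrial phospholipid and respiration, actin and adhesion, kinase and phosphatase signalling, chromatin regulators, membrane traffic, and genes with epithelial-type or neural-type exons as markers of other cell types. Exons were named by a rule set before the data were examined: every PTPMT1 and SRSF1 event, exons called in both comparisons, the 5 largest called differences per direction and comparison with at least 50 informative reads, up to 3 called exons per list, and up to 5 exons per irradiation or interaction result with at least 50 informative reads. The main tests, lists and most alternatives were also fixed then.

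Coordinates are hg19, 1-based, as in the event names. The annotation used was GENCODE 29, made on another build, so no coordinate was converted. Events were matched to its transcripts by gene ID, exon length and the lengths of both flanking introns, and 88.2% of events with a gene ID were matched. Of the 1902 events without an ID, 1570 matched a single gene by structure. Exon numbers and sequences come from those transcripts. The planned motif count on an hg19 genome was not run, and the matched transcripts took its place, a choice made after seeing the data. A planned count of SRSF1 reads was not run, since none of the events used carried that symbol.

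Fisher's exact test, the interaction test and both limma fits were tried on simulated data, with binomial reads at the real depths for 5367 exons and 200 of them changed. At a 2-unit change in log2 odds, Fisher's exact test recovered 17.0% of 100 changed exons in the unirradiated comparison and 14.0% in the irradiated one. The weighted limma fit recovered 24.0% of them, and the unweighted fit recovered 0. The interaction test recovered 6.0% of exons changed by 2 units and 26.0% of those changed by 4 units. None of the 5167 unchanged exons was called by any of these tests. The simulated reads of unchanged exons varied by counting alone, with no variation between cultures. The simulation therefore cannot show how many false calls such variation gives in the real libraries. Of 40 lists of 100 random exons, 1 stood apart by the median absolute difference of simulated read shares. By that measure a list of the raised exons lay at the 96.3rd percentile, inside the bound. A list of all changed exons lay at the 100th. The Bayes factor rule, the interval rule, the called-share percentile of lists and the feature and motif percentiles were not simulated. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and numpy 2.4.6 were used. Alternatives covered the Bayes factor, PSI and read minimums, the calling rule, the counting of events, prior counts, weighting and matching.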

Results

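Exon inclusion was measured by RNA sequencing in H1299 cells, a human lung cancer line, with or without knockdown of SRSF1, a serine and arginine rich protein that binds exons and promotes their splicing. Each state was sequenced unirradiated and after 6 Gy of ionizing radiation, as 1 library per group. The tables held 21582 skipped-exon events for the unirradiated pair and 21235 for the irradiated pair. Informative reads summed over events came to 2036697 in the unirradiated knockdown, 1636712 in the unirradiated control, 1595035 in the irradiated knockdown and 1565463 in the irradiated control, with a read counted at each event it overlaps. Among measured events the median was 64 informative reads in the unirradiated knockdown and between 50 and 52 in the other libraries. The median width of the 95% PSI interval was 0.15 in the former and 0.17 in the latter. With 1 library per group no difference below has a replicate check, and intervals cover the estimate within a library only. The level of SRSF1 was not analysed here, because none of the events used carried its symbol, so the knockdown labels have no check of their own.

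The series title names PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, as an SRSF1 target. Its skipped exon was less included in both knockdown libraries. The exon lies on chromosome 11 from 47591252 to 47591443 (hg19, plus strand), spans 192 nt and matches exon 3 of 4 of a PTPMT1 transcript. The matched transcripts are 3, of which 1 has the exon wholly coding, 1 partly coding and 1 is noncoding. The gene symbol in the tables also names the neighbouring gene NDUFS3. In unirradiated cells PSI was 0.77 (95% interval 0.71 to 0.83) in the control, from 191 inclusion-only and 34 exclusion-only reads. It was 0.52 (0.46 to 0.58) in the knockdown, from 189 and 113 reads, a difference of -0.25 that was called. In irradiated cells PSI was 0.71 (0.65 to 0.77) in the control, from 219 and 59 reads, and 0.52 (0.45 to 0.59) in the knockdown, from 148 and 88 reads. That difference, -0.19, lay just inside the 0.2 minimum and was not called, although the intervals were apart and the authors' deposited table gives a Bayes factor of 7685. The exon did not pass the interaction test for a difference between the 2 effects (Wald test on reads, adjusted p = 0.966). That test recovered few changed exons in simulated data, so a difference is not excluded. By the share of inclusion-only among informative reads, which is not corrected for length, the values were 84.9% (exact binomial interval 79.5 to 89.3), 62.6% (56.9 to 68.1), 78.8% (73.5 to 83.4) and 62.7% (56.2 to 68.9) in the same order. The sequence of the exon is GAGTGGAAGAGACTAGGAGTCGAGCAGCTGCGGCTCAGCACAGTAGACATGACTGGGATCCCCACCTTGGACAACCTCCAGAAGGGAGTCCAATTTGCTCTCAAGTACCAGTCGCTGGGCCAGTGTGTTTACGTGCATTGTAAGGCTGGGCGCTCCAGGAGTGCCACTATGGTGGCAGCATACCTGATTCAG.

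**Figure D1:**
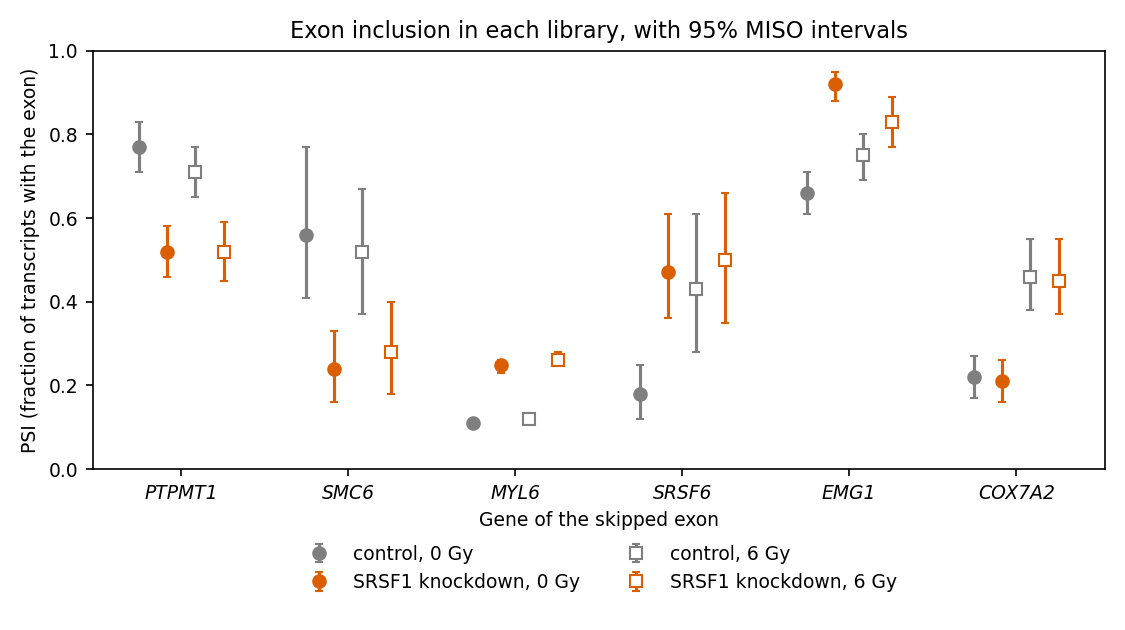
PSI of 6 skipped exons (y axis, a fraction from 0 to 1) in each of the 4 libraries, with points for the posterior mean and bars for the 95% MISO interval. PTPMT1 stands at 0.52 in both knockdown libraries, against 0.77 and 0.71 in the controls. The PSI of COX7A2 differs by irradiation, not by knockdown, although the weighted fit did not pass it for irradiation.

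In unirradiated cells, 70 of 6900 measured exons were called between the knockdown and the control library, 25 with higher and 45 with lower inclusion in the knockdown. Lower inclusion thus made up 64.3% of calls (exact binomial interval 51.9 to 75.4). This interval, like those for shares of exons below, treats exons as independent. Among well covered exons, SRSF6, itself an SR protein, had PSI 0.18 (0.12 to 0.25) in the control and 0.47 (0.36 to 0.61) in the knockdown at a 268-nt exon annotated in a transcript subject to nonsense-mediated decay (chromosome 20, 42087793 to 42088060). The 150-nt exon 5 of EMG1, a ribosome assembly methyltransferase, went from 0.66 (0.61 to 0.71) to 0.92 (0.88 to 0.95), on chromosome 12 from 7084391 to 7084540. PLEKHM2, a lysosome transport adaptor, had PSI 0.26 in the control and 0.52 in the knockdown at a coding 60-nt exon. Lower inclusion was called for MON1A, with PSI 0.73 in the control and 0.40 in the knockdown, and for ARMC10, with 0.86 and 0.48. SREK1, a splicing regulator, had 0.84 and 0.45, and IDH3B, a subunit of mitochondrial isocitrate dehydrogenase, had 0.84 and 0.28. The ARMC10, SREK1 and IDH3B calls rest on 0 exclusion-only reads in the control and 4, 8 and 4 in the knockdown. RP11-186B7.4, which had no match in the annotation used, had 0.86 and 0.55 at an 18-nt exon, although its reads did not differ by Fisher's exact test (unadjusted p = 0.412). For LSM2, with PSI 0.61 and 0.92, the informative reads moved against PSI, as they did in 4 of the 70 calls. By Fisher's exact test on the reads, 31 exons passed an adjusted p of 0.05, and 9 of these differed by at least 0.2 in PSI. IDH3B differed the other way in irradiated cells, by 0.18, and was not called there.

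Of the fixed gene lists, 2 had a larger share of called exons than matched random lists in unirradiated cells. They are among 66 list percentiles computed over both comparisons, a number at which some can pass the bounds by chance. Of 108 exons of DNA damage response and repair genes, 4 were called, all lower in the knockdown (98.1st percentile); at a Bayes factor of 20 only 2 were (87.0th percentile). They include SMC6, a subunit of the SMC5/6 repair complex, at an 87-nt exon of the 5′ UTR (chromosome 2, 17934245 to 17934331): PSI was 0.56 (0.41 to 0.77) in the control and 0.24 (0.16 to 0.33) in the knockdown. NEIL2, a DNA glycosylase, had 0.40 and 0.07 at a 162-nt exon of the 5′ UTR. It had 12 inclusion-only and 4 exclusion-only reads in the control, and 5 and 16 in the knockdown. Of 27 exons of reported SRSF1 targets, 2 were called (98.5th percentile): PTPMT1, lower, and NUMA1, a spindle protein, higher at a 42-nt coding exon with PSI 0.14 in the control and 0.38 in the knockdown. PTPMT1 is on that list as the gene of this series, and without it 1 of 26 exons was called (87.4th percentile). In irradiated cells NUMA1 differed the other way, by -0.09, and was not called. NUMA1 also counts among the cell cycle genes, where 3 of 102 exons were called, all higher. The others were ECT2, a cytokinesis exchange factor, with 0.14 and 0.47, and STAG2, a cohesin subunit, with 0.13 and 0.39 at a 5′ UTR exon. Among 122 exons of chromatin regulators 2 were called higher, in ASXL1 and KAT6A, though ASXL1 differed by -0.14, uncalled, in irradiated cells. Among 140 of actin and adhesion genes 2 were called lower, in MACF1 and PLEC. The MACF1 exon of 9 nt had 85 inclusion-only and 0 exclusion-only reads in the control, and 5 of each in the knockdown; for PLEC the informative reads moved against PSI. Among 97 exons of mitochondrial genes, PTPMT1 and IDH3B were called lower, and of 105 of splicing factor genes SRSF6 was called higher. None was called among 41 of apoptosis genes, 103 of kinase and phosphatase genes, 75 of membrane traffic genes and 43 of the genes marking other cell types.

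In irradiated cells, 45 of 6412 measured exons were called between knockdown and control, 24 higher and 21 lower in the knockdown. Lower inclusion made up 46.7% of them (exact binomial interval 31.7 to 62.1). CENPN, a centromere protein, had PSI 0.54 (0.37 to 0.73) in the control and 0.91 (0.77 to 0.99) in the knockdown at a coding 102-nt exon. GTPBP8 had 0.54 and 0.86, and RNH1, the ribonuclease inhibitor, had 0.46 and 0.72 at a 5′ UTR exon. ZNF410, a zinc finger gene, had 0.72 and 0.95. Lower inclusion was called for VEZT, an adherens junction protein, with 0.97 in the control and 0.76 in the knockdown. It was also called for an 87-nt exon of KIAA1191, with 0.92 and 0.67. The CENPN, GTPBP8 and ZNF410 calls rest on 10, 6 and 6 exclusion-only reads in the control and 0 in the knockdown, and that of VEZT on 0 and 9. In unirradiated cells CENPN differed the other way, by -0.04, and was not called. No list stood apart by its share of calls. Of the list genes, OSBPL3 and AP1B1 were the 2 called of 83 membrane traffic exons, both higher, and OSBPL3 was also the 1 called of 32 exons marking other cell types. Neither was called in unirradiated cells, where OSBPL3 differed the other way, by -0.17, and AP1B1 had PSI 0.04 in both libraries. After irradiation RAD54B was called lower among 100 exons of repair genes, PRMT2 among 108 of chromatin regulators and VEZT among 128 of actin and adhesion genes. Some of these calls rest on few reads. RAD54B had 4 inclusion-only and 6 exclusion-only reads in the control, and 1 and 22 in the knockdown. For PRMT2 they were 26 and 5 in the control and 7 and 6 in the knockdown, and for OSBPL3 9 and 7, and 18 and 0. None was called among 113 exons of splicing factor genes, 23 of reported SRSF1 targets, 38 of apoptosis, 99 of cell cycle, 89 of mitochondrial and 98 of kinase and phosphatase genes. By Fisher's exact test 12 exons passed, of which 2 differed by at least 0.2.

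The 2 knockdown comparisons share no library, so each can be set against the other. Of 5367 exons measured in all 4 libraries, 63 were called in unirradiated and 39 in irradiated cells, and 2 were called in both in the same direction. Independent lists would share 0.0894 exons among the higher and 0.138 among the lower. One was a 106-nt exon of the 5′ UTR of KIAA1191, with PSI 0.55 in the control and 0.12 in the knockdown, and 0.61 and 0.17 after irradiation, on 12 to 17 informative reads per library. An overlapping 87-nt exon of KIAA1191 held the same exclusion-only reads, with 55 to 93 inclusion-only reads per library against 4 to 11. Its PSI was 0.89 in the control and 0.72 in the knockdown, and 0.92 and 0.67 after irradiation. It was called in the irradiated pair alone. The other exon called in both was RPLP1, a ribosomal stalk protein, with 0.45 and 0.71, and 0.67 and 0.90 after irradiation. That event spans 1641 nt, is annotated as noncoding, rests on 1 to 4 exclusion-only reads per library, and also differed by 0.22 and 0.19 with irradiation. Of exons called in unirradiated cells, 44 of 63 had the same sign in irradiated cells (69.8%, exact binomial interval 57.0 to 80.8), with a median difference of 0.07 in that direction against 0.31 where they were called. Of exons called in irradiated cells 23 of 39 had the same sign in the other pair (59.0%, 42.1 to 74.4). Across the 5367 exons the knockdown differences had Pearson's r = 0.144 and Spearman's rho = 0.118; exons are not independent replicates. With at least 50 informative reads in each library r was 0.25 over 2690 exons. With no read minimum, or on log2 ratios of reads, r was lower than over all exons, as given further below.

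**Figure D2:**
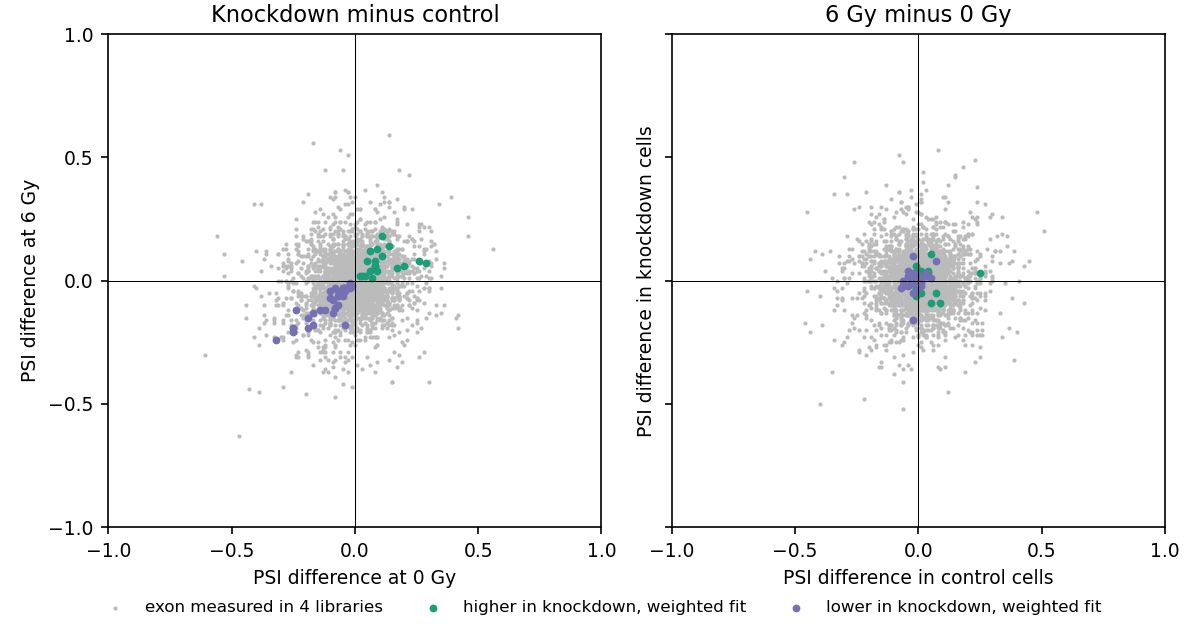
PSI differences of 5367 exons measured in all 4 libraries, knockdown minus control at 0 and 6 Gy (left) and 6 Gy minus 0 Gy in control and knockdown cells (right), both axes as fractions. The coloured exons, 19 higher and 31 lower in the knockdown by the weighted fit, were chosen on these data, so that they share a sign at left is no test; r there is 0.144 over all exons, against 0.0115 at right.

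No exon passed the read-level Wald test, with Benjamini-Hochberg adjustment, for a knockdown effect that differed between unirradiated and irradiated cells. Of 5367 exons, 192 had an unadjusted p under 0.05 by this test, and the smallest adjusted p was 0.345. In simulated data it recovered 6.0% of exons changed by 2 units of log2 odds and 26.0% at 4 units. The lack of passing exons therefore does not show that the 2 effects were equal. The planned additive limma fit over the 4 libraries also called 0 exons, with 395 at an unadjusted p under 0.05. That fit recovered none of the changed exons in simulated data. The same fit weighted by counting variance, an alternative set beforehand with the 0.2 minimum, called 3 exons, in PTPMT1, SMC6 and TNFRSF12A, all lower. Without that minimum, a choice made after seeing the data, 50 exons passed, 19 higher and 31 lower. By Fisher's exact test on the reads, 35 of the 50 had an unadjusted p under 0.05 in both pairs and 15 in the unirradiated pair alone. All 50 had the same sign in both comparisons, and the median of their absolute mean differences was 0.085. The fit that picked these exons used the same 4 libraries, so neither the shared sign nor the counts by Fisher's exact test are a separate check. The examples that follow were chosen after their values were seen. MYL6, a myosin light chain, had PSI 0.11 (0.11 to 0.12) and 0.12 (0.11 to 0.13) in the controls and 0.25 (0.23 to 0.26) and 0.26 (0.25 to 0.28) in the knockdown at a 45-nt exon on chromosome 12 from 56554410 to 56554454. Its log2 odds rose by 1.38 ± 0.06 (SE; weighted limma, adjusted p = 9.4e-106). An exon on chromosome 3 from 52232688 to 52232864, without a symbol in the tables, matches exon 2 in the 5′ UTR of ALAS1, the first enzyme of haem synthesis, and had 0.31 in both controls and 0.12 in both knockdown libraries. EPHA2, a receptor tyrosine kinase, had 0.94 and 0.90 in the controls and 0.80 and 0.78 in the knockdown. PTPMT1 passed with a log2 odds change of -1.40 ± 0.22 (SE, weighted limma, adjusted p = 2.7e-07). In the unweighted limma fit the adjusted p was 0.647 for both MYL6 and PTPMT1. The weights come from read counts, so the small p-values of the weighted fit rest largely on read numbers and do not measure spread between cultures.

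By list, the weighted limma fit without a PSI minimum passed 5 of 95 exons of splicing factor genes: SRSF6, TRA2B and NONO higher, HNRNPA2B1 and CPSF6 lower, with the same 5 when adjusted over the list alone. NONO and SRSF6 rest on the unirradiated pair: NONO had PSI 0.04 in the control and 0.11 in the knockdown there, against 0.05 and 0.06 irradiated (Fisher's exact test, unadjusted p = 0.361), and for SRSF6 the irradiated pair gave an unadjusted p of 0.460. The TRA2B exon of 276 nt, annotated in a transcript subject to nonsense-mediated decay, had PSI 0.29 and 0.30 in the controls and 0.34 and 0.38 in the knockdown. The 36-nt exon 2 of HNRNPA2B1, which distinguishes its B1 from its A2 protein, had 0.18 and 0.15 in the controls and 0.11 in both knockdown libraries. Of 116 exons of actin and adhesion genes 3 passed, MYL6 and MARK3 higher and PXN lower, and 4 when adjusted over the list alone, with ITGA6 added. Of 80 mitochondrial exons 3 passed, 2 overlapping exons of UQCRB higher and PTPMT1 lower, and 4 when adjusted over the list alone, with another UQCRB exon added. The 2 overlapping UQCRB exons held the same exclusion-only reads, so they are not separate observations. One passed among 76 exons of repair genes, SMC6, and 1 among 20 of reported SRSF1 targets, PTPMT1, with the same counts adjusted over the list alone. None passed among the other 6 lists by either adjustment.

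The density of GGA, the triplet at the core of purine-rich SRSF1 sites, differed with the direction of change. Exons called lower in unirradiated knockdown cells held 3.15 GGA per 100 nt over 38 exons with a matched sequence, against 2.22 in 6289 uncalled exons (100th percentile of matched random sets). Those called higher held 1.78 over 24 exons (5.73rd percentile). In irradiated cells the called-lower exons held 3.06 over 20 exons (99.7th percentile) and the called-higher ones 1.11 over 21 exons (0th percentile), against 2.22 in 5875 uncalled exons. The 28 lower exons of the weighted fit without a PSI minimum held 3.47 and its 19 higher exons 0.597, against 2.24 in 4894 other exons (100th and 0th percentile). The longer motifs GGAGA and GAAGA lay inside the percentile bounds in all 4 called sets. In the weighted fit GGAGA lay at the 1.90th percentile in the higher exons and the 97.2nd in the lower ones, or the 97.3rd in a second random draw. GAAGA lay at the 41.7th in the higher and the 34.6th in the lower exons of that fit. These are 18 percentiles on 3 motifs, in exon sequences taken from matched transcripts, a choice made after seeing the data.

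**Figure D3:**
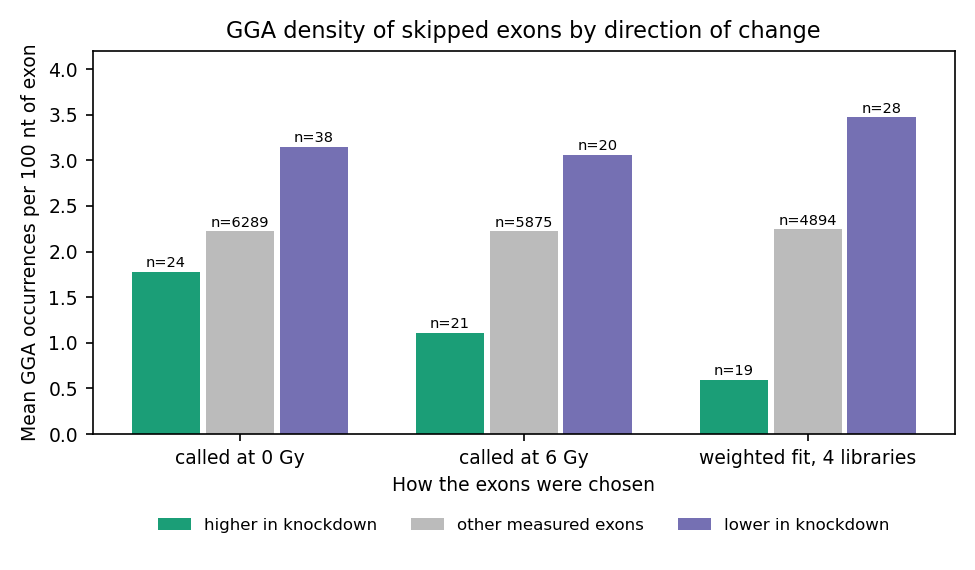
Mean number of GGA triplets per 100 nt of skipped exon (y axis, from 0) for exons higher or lower in the knockdown and for other measured exons, with the number of exons above each bar and no error drawn. Lower exons hold between 3.06 and 3.47, other exons 2.22 to 2.24 and higher exons between 0.597 and 1.78.

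Called exons in unirradiated cells had short upstream introns, with medians of 643 nt for higher and 1176 nt for lower exons against 2301 nt in uncalled ones (0.11th and 1.91st percentile of matched sets). In irradiated cells the medians were 1809 and 2326 nt (30.8th and 49.9th percentile). Exon lengths were divisible by 3 in 13 of 25 higher and 19 of 45 lower exons in unirradiated cells, and in 13 of 24 and 6 of 21 in irradiated cells. None of these shares, nor exon length or downstream intron length, lay outside the percentile bounds, among 16 percentiles computed.

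With irradiation, 21 exons changed in control cells by the interval rule, 13 higher and 8 lower at 6 Gy, and 37 in knockdown cells, 25 higher and 12 lower. By the same rule over the same 5367 exons, 56 changed with knockdown in unirradiated and 27 in irradiated cells. COX7A2, a subunit of cytochrome c oxidase, had a coding 109-nt exon (chromosome 6, 75949993 to 75950101) whose PSI was 0.22 (0.17 to 0.27) unirradiated and 0.46 (0.38 to 0.55) irradiated in control cells, and 0.21 (0.16 to 0.26) and 0.45 (0.37 to 0.55) in knockdown cells. Its inclusion-only and exclusion-only reads were 84 and 22 unirradiated and 132 and 14 irradiated in control cells. In knockdown cells they were 66 and 15, and 128 and 13. The weighted limma fit did not pass this exon for irradiation (adjusted p = 0.512). In all, 2 exons changed in both control and knockdown cells in the same direction. In control cells MTRR, methionine synthase reductase, had 0.34 unirradiated and 0.70 irradiated, FAM82B had 0.69 and 0.96, and SRSF6 had 0.18 and 0.43. GPX8, a glutathione peroxidase of the endoplasmic reticulum, had 0.91 and 0.61. Their differences with irradiation in knockdown cells were 0.14 for MTRR, 0.03 for FAM82B, 0.03 for SRSF6 and 0.01 for GPX8. MTRR, SRSF6 and GPX8 were also called with knockdown in unirradiated cells, so both results rest on the same unirradiated control library. In knockdown cells PPP1R12A, a myosin phosphatase subunit, had 0.47 and 0.79, C12orf52 had 0.55 and 0.81, and the 18-nt exon of RP11-186B7.4 had 0.55 and 0.89. CD164 had 0.82 and 0.55, and RBM27, an RNA-binding protein, had 0.84 and 0.49. By Fisher's exact test with Benjamini-Hochberg adjustment and the same PSI minimum, 1 exon passed in each irradiation comparison.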

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

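The results below were recomputed with 1 choice changed at a time, or 2 where both are named; the read odds ratios of named exons, the counts of calls whose reads move with PSI, the irradiation correlation, the fits without a PSI minimum, the SRSF1 target list without PTPMT1, Fisher's test per pair in the weighted fit and the transcript-based motif counts with their controls were chosen after seeing the data. Counts of called exons moved with the thresholds, since stricter ones keep fewer exons by construction. Unirradiated calls, 70 as reported, were 108 at a Bayes factor of 5, 32 at 100, 41 at a PSI difference of 0.3, 30 with at least 50 informative reads, 44 with 1 event per gene and 9 by Fisher's exact test. Irradiated calls, 45 as reported, were 68, 27 and 7 at Bayes factors of 5, 20 and 100, 22 and 11 with at least 20 and 50 reads, and 2 by Fisher's exact test. Exons called in both comparisons, 2 as reported, were 6 at a Bayes factor of 5 and 10 at a PSI difference of 0.1. They were 1 at a PSI difference of 0.3, with 20 or 50 reads or by intervals, and 0 at Bayes factors of 20 and 100, by Fisher's exact test or with 1 event per gene. Exons changed with irradiation in control cells, 21 as reported, were 38 and 12 at PSI differences of 0.1 and 0.3, 8 with at least 50 reads and 1 by Fisher's exact test. In knockdown cells, 37 as reported, they were 67, 19, 13 and 1 in the same order. The correlation of knockdown differences, 0.144 as reported, was 0.0986 with no read minimum, 0.180 and 0.25 with at least 20 and 50 reads, 0.0887 on log2 ratios of reads, and 0.0115 between the irradiation comparisons. The interaction count stayed at 0 in each of the alternatives run on it. The additive count, 0 as reported, was 3 with weights and 50 with weights and no PSI minimum, and 0 in the other alternatives run. Percentiles of called share and median difference standing apart over the lists, 2 as reported, were 6 without matching on reads. They were again 2 at a Bayes factor of 20, but DNA repair fell to the 87.0th percentile in unirradiated cells and cell cycle rose to the 97.9th. Without PTPMT1 the SRSF1 target list fell to the 87.4th percentile there. GGAGA in the higher exons of the weighted fit, at the 1.90th percentile and past the bound, was inside it at 2.87 matched on length alone, 3.87 matched on G+C content and 2.97 with 1 exon per gene. As a share of inclusion-only reads PTPMT1 stood at 0.849 and 0.626 in unirradiated control and knockdown, and 0.788 and 0.627 in irradiated ones, above PSI since that share is not corrected for length. LSM2 and PLEC reversed between PSI and reads, with log2 odds ratios of -0.75 and 0.67 against PSI differences of 0.31 and -0.26. Except where named above as due to construction, the cause was not tested. With 1 library per group no replicate could be left out. The additive fit compares knockdown with control within each irradiation state; the labels hold no other pairing. Motif counts on an hg19 genome and SRSF1 reads were not run.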

Other observations

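The tests on the irradiation correlations, on motifs in matched transcripts and on PTPMT1 were chosen only after the results were seen. Beyond the lists, the exons of the weighted fit without a PSI minimum include the following, which were chosen after their values were seen and no enrichment was tested. MRPS28, a mitochondrial ribosomal protein, had PSI 0.84 and 0.78 in the controls and 0.67 and 0.65 in the knockdown at a 182-nt coding exon. RPL10 had 0.93 in both controls and 0.90 in both knockdown libraries, on at least 407 exclusion-only reads per library. TNFRSF12A, the TWEAK receptor, had 0.56 and 0.49 in the controls and 0.31 and 0.28 in the knockdown at the 131-nt exon called in the weighted fit. An overlapping 105-nt exon, with the same exclusion-only reads, had 0.95 in both controls and 0.88 and 0.89 in the knockdown. NGFRAP1 had 0.72 and 0.75 in the controls and 0.55 and 0.57 in the knockdown at a 5′ UTR exon. UAP1, an enzyme of UDP-sugar synthesis, had 0.07 and 0.11 in the controls and 0.18 and 0.21 in the knockdown at a coding 51-nt exon. With irradiation the weighted fit passed 2 exons, both overlapping exons of the 5′ UTR of HNRNPC. The 26-nt one had PSI 0.81 in control and 0.82 in knockdown cells unirradiated, and 0.76 and 0.74 irradiated. The mean PSI difference of membrane traffic exons was 0.0320 in irradiated cells (99.9th percentile) and -0.00147 in unirradiated cells (51.3rd percentile), among 66 list percentiles computed. Their median difference was 0 in irradiated cells, and the median absolute difference lay at the 49.2nd percentile, so the shift was in the mean alone.

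Knockdown differences ran the same way in both comparisons, at r = 0.144, and without the exons called in either comparison or past the weighted fit r was 0.114 over 5224 exons, which argues against a few exons carrying it. Among 1799 exons whose scaled event reads changed by under 0.25 (log2) in both comparisons it was 0.188, so the correlation was also present where read numbers changed little. These exons were not matched on informative reads, and r rose with those, from 0.0996 in the group starting at 10 reads to 0.391 at 200 or more. Whether changed read numbers add to the correlation therefore cannot be told. The irradiation comparisons had r = 0.0115 over all exons, which argues against a pattern that any pairs of libraries give; at 200 or more informative reads, though, it was 0.277 against 0.391 for knockdown (Spearman's rho 0.0851 against 0.181), so for these exons that explanation stays open. SRSF1-type sites are a candidate biological source, but GGAGA density in the lower exons lay at the 97.3rd percentile (n = 28; 97.2 in another random draw), at 97.8 matched on length alone, and at 98.0 both matched on G+C content and with 1 exon per gene, on either side of the upper bound. GAAGA density in the same lower exons lay at the 34.6th percentile. Any other difference between knockdown and control cultures stays open.

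In the weighted fit without a PSI minimum, GGA was denser in exons lower in the knockdown and sparser in exons higher in it. With random sets matched on exon length and G+C content these lower exons lay at the 100th percentile and the higher ones at the 0th, so G+C content does not account for it in this fit; the called exons were not matched on G+C content. With 1 exon per gene the values were again the 100th (25 exons) and 0th (18 exons), so repeated exons of a gene do not either. The reverse complement TCC lay at the 28.7th and 68.1st percentiles under G+C matching. Whether SRSF1 binds these exons was not tested, and other factors that bind purine-rich exons stay open.

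The lower inclusion of PTPMT1 exon 3 was weighed against shared reads and read number. Scaled exclusion-only reads were 2.67-fold (exact interval 1.8 to 4.04) in knockdown over control unirradiated and 1.40-fold (0.998 to 1.99) irradiated, so a loss of reads inside the exon alone is not excluded in the irradiated pair. Of the annotated transcripts there, 1 of NDUFS3 joins the exon's neighbours and skips it, so reads of NDUFS3 stay open in both pairs. The scaled event reads changed by at most 1.13-fold, so the number of reads at the event as a whole changed little. That total can hold NDUFS3 reads too, so it cannot tell whether the reads of PTPMT1 alone changed. Both tests compare these libraries, so another difference between the cultures stays open beside an effect of SRSF1.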
